A study of Mus musculus with 12 samples.

How the data were processed

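Left ventricular tissue of 12 mice was used, in 3 groups of 4: Sham vehicle, UNX/DOCA vehicle and UNX/DOCA ITF2357. Per the labels the replicates of a group are different animals, with 1 library each. About 10 mg of tissue gave the RNA, and poly(A)-selected, strand-specific libraries were sequenced in pairs of 150 bp reads. The deposited table holds raw counts per Ensembl gene, with no normalization by the authors. Per the submitters' processing notes, reads were checked with FastQC 0.11.9 and aligned with STAR 2.7.10b to the mm39 build of the mouse genome. The counting tool, its strand setting, the annotation release and any read filter are not given in the sources used here, so reads from the opposite strand cannot be told apart from a gene's own. The values were checked to be whole numbers of 0 or more with different totals per library. A treatment field of the labels numbers the 4 drug libraries differently from their titles, which all name ITF2357, and the titles were used for grouping.

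Total counts per library ran from 23.4 to 34.9 M, which at 28.3 M on average puts 1 CPM at about 28 reads. Counts between replicates varied 10.9 to 57.3 times more than counting error alone (chi-square per degree of freedom). Gene symbols came from a reference annotation of the GRCm38 build by Ensembl identifier, positions were not used, and genes with a symbol held at least 99.2% of each library's counts. Genes on the Y chromosome and Xist were looked at for mixed-up samples, and 0 libraries stood out. Over the 12 libraries Ddx3y ran from 52.5 to 103 CPM and Xist from 0.456 to 1.81 CPM. All libraries thus look male, so this check cannot show a swap between them.

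Genes were tested with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr (10 counts at the average depth), TMM scaling, and a quasi-likelihood fit with robust dispersion over all 12 libraries with a term per group, which left 9 residual degrees of freedom and a common biological coefficient of variation of 0.187. This kept 16981 genes, of which 15957 have a symbol. Quasi-likelihood F tests were made for the 3 contrasts between groups, with Benjamini-Hochberg adjustment over all genes in each contrast and a threshold of 0.05. Every adjusted p of a gene is from this test unless another tool is named. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values are TMM-scaled, and list scores and principal components used log2 CPM with a prior count of 2. Replicate numbers do not pair animals across groups: over the 12 pairs of libraries with the same number in 2 groups, centred expression correlated between -0.19 and 0.25 (median 0.00). The test was also tried on simulated data in which 200 genes were given a change. These were a single draw per contrast from the means and dispersions fitted by edgeR. They had the same spread in each group and no correlation between genes.

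Before the data were examined, 52 gene lists for cardiac muscle, matrix, metabolism, signalling and cell types, the comparisons, the settings to vary and the rule for naming genes were fixed. The lists come from general knowledge and not from these libraries, and list genes without enough counts were left out. Lists were tested with camera from limma 3.58.1 at an inter-gene correlation of 0.01, adjusted over the 52 lists. The test was repeated with the correlation estimated from the data and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. Within a list, p values were also adjusted over the list alone.

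The rule named, for each contrast with ITF2357, the called genes with the largest change among those with an approved symbol, at least 1 CPM in the higher group and no overlap between groups. These were 8 up and 8 down against UNX/DOCA vehicle and 5 up and 5 down against Sham vehicle. For a contrast with 0 calls it named the 3 smallest p in each direction as values that did not pass. It always named Nppa, Nppb, Myh7, Myh6, Acta1, Col1a1, Col3a1, Postn, Fn1 and Atp2a2, and the HDAC genes as a group. In the first 2 contrasts it named up to 4 genes with the smallest p of each list described, and the text uses fewer for most lists.

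Settings varied were RLE scaling, upper-quartile scaling, library totals, no filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with sample weights, a fit of only the 2 groups compared, a replicate block, a test against a 1.2-fold change (glmTreat), and each of the 12 libraries left out. Added after the data were seen were the first component of a list of clock genes as a covariate, the mean of immediate early genes as a covariate, UNX/DOCA vehicle replicates 3 and 4 left out together, and a slope over genes with an unadjusted p under 0.05. Also added then were the share of opposite signs in simulated and divided libraries, and list tests with an estimated correlation without UNX/DOCA vehicle replicates 3 and 4. For the relation across genes, unchanged groups were simulated 20 times from the fitted means and dispersions, and the UNX/DOCA vehicle libraries were divided between the contrasts in all 6 ways. Each contrast was also compared with every division of its 8 libraries into 4 and 4, fitted by the same model. Transcript isoforms, splicing and reads outside genes were not analysed here.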

Results

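Poly(A) RNA of the left ventricle was sequenced from 12 mice in 3 groups, with 4 animals and 1 library per animal in each group. Sham vehicle mice had a sham operation. UNX/DOCA vehicle mice had a kidney removed and were given deoxycorticosterone acetate, a mineralocorticoid that together with kidney loss gives a mouse model of diastolic dysfunction. UNX/DOCA ITF2357 mice had the same operation and received chow with ITF2357 (givinostat), an inhibitor of histone deacetylases (HDACs), from 4 weeks after surgery for 4 weeks, while the vehicle groups ate control chow. No Sham group received ITF2357, so an effect of the drug in hearts without UNX/DOCA is not measured here. Total counts per library ran from 23.4 to 34.9 M. The mean was 28.2 ± 4.51 M in Sham vehicle, 28.0 ± 3.58 M in UNX/DOCA vehicle and 28.7 ± 3.27 M in UNX/DOCA ITF2357 (SD, n = 4). Mitochondrially encoded genes took 25.5% ± 0.727 of the counts in Sham vehicle, 25.3% ± 1.33 in UNX/DOCA vehicle and 26.2% ± 1.495 in UNX/DOCA ITF2357 (SD, n = 4). Enough counts to be tested were found for 16981 genes. Expression is given below as TMM-scaled CPM (counts scaled to a common library size), as mean ± SD over 4 libraries.

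The first comparison, UNX/DOCA vehicle against Sham vehicle, asked what the operation and mineralocorticoid did to the ventricle. As lists, camera called fetal and hypertrophic genes, macrophage genes, proteoglycans and other matrix genes higher in UNX/DOCA vehicle, and ion channel, calcium handling and erythroid genes lower. None of these calls held when the correlation between genes was estimated (adjusted p = 0.432 to 0.484 with an estimated correlation). Nppa, which encodes the atrial natriuretic peptide and marks a loaded ventricle, averaged 283 ± 45.8 CPM in UNX/DOCA vehicle and 114 ± 36.9 in Sham vehicle, a 2.49-fold ratio with no overlap between the groups (n = 4 and 4). It did not pass over all genes (adjusted p = 0.161). No single gene passed: edgeR called 0 of 16981 genes, with the smallest adjusted p at 0.0649. Yet 2699 genes had an unadjusted p under 0.05 where 849 would be expected by chance. In fits of the 8 libraries alone the real groups had 2558 such genes, the most of 35 divisions into 4 and 4. A division across the groups, UNX/DOCA vehicle replicate 1 with Sham vehicle replicates 1, 2 and 4 against the rest, had 2538. The next highest had 1709. The division with 2538 keeps most libraries of each group together, so it cannot show whether the excess belongs to the groups. DESeq2 called 593 genes (404 up, 189 down) and limma-voom 521 (324 up, 197 down). In simulated data 24 of 136 calls of DESeq2 were false, against 7 of 98 for edgeR and 6 of 93 for limma-voom. The simulated data were drawn from dispersions fitted by edgeR, which may favour it. The groups were fully separated in 9.39% of genes, where chance gives 2.86%.

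Of 52 gene lists, camera called 18 higher and 6 lower in UNX/DOCA vehicle, and 0 of these 24 calls held with an estimated correlation. Fetal and hypertrophic genes had a median log2 fold change of 0.39 over 18 measured genes (camera adjusted p = 2.5e-05, adjusted p = 0.462 with an estimated correlation). Adjusted over the list alone 7 of them were higher, against 0 over all genes. Ankrd1, a stretch-responsive cardiac repressor, averaged 1326 ± 163 CPM against 809 ± 206 (log2 fold change 0.71 ± 0.17 SE, adjusted p = 0.117). Rcan1, a target and inhibitor of calcineurin, had a log2 fold change of 0.74 ± 0.20 (adjusted p = 0.134). Skeletal actin Acta1 had 1.04 ± 0.43 (adjusted p = 0.281). The myosin genes Myh7 (0.41 ± 0.22, adjusted p = 0.377) and Myh6 (-0.23 ± 0.11, adjusted p = 0.341) did not pass either. Nor did Nppb (-0.17 ± 0.34, adjusted p = 0.844), which encodes the brain natriuretic peptide. Ion channels had a median of -0.29 over 27 genes, with 8 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 3.0e-05, adjusted p = 0.432 with an estimated correlation). Kcnj3, a potassium channel subunit, averaged 35.2 ± 4.81 against 55.2 ± 2.37 CPM (adjusted p = 0.0954). Abcc9, the sulfonylurea receptor of cardiac potassium channels, averaged 306 ± 43.6 against 446 ± 18.6 (adjusted p = 0.0954). Calcium handling genes had a median of -0.15 over 23 genes, with 4 lower and 1 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00053, adjusted p = 0.462 with an estimated correlation). In that list Atp2a2, the calcium pump of the sarcoplasmic reticulum, averaged 11412 ± 356 against 13842 ± 997 CPM (log2 fold change -0.28 ± 0.06, adjusted p = 0.0998). The release channel gene Ryr2 had -0.39 ± 0.11 (adjusted p = 0.136) and the calcium channel subunit Cacnb2 had -0.41 ± 0.10 (adjusted p = 0.117).

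Of 11 matrix, fibroblast and TGF-beta lists, camera called 10 higher in UNX/DOCA vehicle (adjusted p = 0.432 to 0.484 with an estimated correlation), and basement membrane genes were not called (median -0.03, camera adjusted p = 0.328). Proteoglycans had a median log2 fold change of 0.40 over 14 genes, with 6 higher and 1 lower adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00014, adjusted p = 0.432 with an estimated correlation). In that list Lum averaged 78.0 ± 7.997 CPM against 54.8 ± 6.95 (adjusted p = 0.0998). Vcan averaged 50.8 ± 16.3 against 22.04 ± 3.90 (adjusted p = 0.0998) and Prg4 43.8 ± 26.97 against 7.73 ± 1.76 (adjusted p = 0.127). Matrix proteases and their inhibitors (26 genes, median 0.46, 4 higher adjusted over the list alone, 0 over all genes) had a camera adjusted p of 0.00078 and adjusted p = 0.484 with an estimated correlation. Timp1, an inhibitor of matrix metalloproteinases, averaged 8.94 ± 3.26 against 2.60 ± 1.47 CPM (adjusted p = 0.120). Collagen processing genes (25 genes, median 0.24, 5 higher adjusted over the list alone, 0 over all genes) had a camera adjusted p of 0.00093 and adjusted p = 0.484 with an estimated correlation. Loxl2, a collagen crosslinking enzyme, had a log2 fold change of 0.76 ± 0.18 (adjusted p = 0.108). Resident fibroblast genes (19 genes, median 0.28, 7 higher adjusted over the list alone, 0 over all genes) had a camera adjusted p of 0.00095 and adjusted p = 0.484 with an estimated correlation. In it Medag stood at 1.14 ± 0.24 (adjusted p = 0.0954). Elastic fibre genes (19 genes, median 0.27, 5 higher adjusted over the list alone, 0 over all genes) had a camera adjusted p of 0.0036 and adjusted p = 0.484 with an estimated correlation. Here Mfap5 stood at 1.38 ± 0.27 (adjusted p = 0.0954). Other collagens (16 genes, median 0.40, camera adjusted p = 0.0036, adjusted p = 0.484 with an estimated correlation) included Col14a1 at 1.15 ± 0.28 (adjusted p = 0.117). Of them 3 were higher and 1 lower adjusted over the list alone, and 0 over all genes. Fibrillar collagens (7 genes, median 0.37, 2 higher adjusted over the list alone, 0 over all genes) had a camera adjusted p of 0.012 and adjusted p = 0.484 with an estimated correlation. In that list Col3a1 stood at 0.56 ± 0.22 (adjusted p = 0.253) and Col1a1 at 0.37 ± 0.26 (adjusted p = 0.523). Postn, a secreted matricellular protein of activated fibroblasts, averaged 76.5 ± 18.8 against 38.7 ± 17.8 CPM (adjusted p = 0.183). The fibronectin gene Fn1 averaged 62.5 ± 28.6 against 44.4 ± 5.51 (adjusted p = 0.369). TGF-beta targets (20 genes, median 0.42, camera adjusted p = 0.0012), matricellular proteins (19 genes, median 0.28, camera adjusted p = 0.0076) and activated fibroblast genes (18 genes, median 0.25, camera adjusted p = 0.033) were also called higher, with adjusted p = 0.484 with an estimated correlation for each. Adjusted over the list alone, 3, 4 and 3 of their genes were higher, and 1 matricellular and 1 activated fibroblast gene were lower, against 0 over all genes. Without UNX/DOCA vehicle replicate 3 the calls of elastic fibres (camera adjusted p = 0.220), matricellular proteins (0.183), fibrillar collagens (0.123) and activated fibroblasts (0.175) ended. The fibrillar collagen call also ended without UNX/DOCA vehicle replicate 1 (0.113) and Sham vehicle replicate 3 (0.0600). That of activated fibroblasts ended without the same libraries (0.104 and 0.125) and Sham vehicle replicate 2 (0.0769).

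Of 8 immune lists, camera called 5 higher in UNX/DOCA vehicle (adjusted p = 0.484 to 0.724 with an estimated correlation), mainly through 2 of its 4 libraries. Interferon response genes (median 0.16, camera adjusted p = 0.128), T and NK cell genes (0.10, 0.964) and B cell genes (-0.07, 0.374) were not called. The macrophage and monocyte list had a median log2 fold change of 0.66 with 21 of 22 genes above 0 (camera adjusted p = 6.2e-06, adjusted p = 0.484 with an estimated correlation). In it 0 genes passed adjusted over the list alone or over all genes. Its score, a mean log2 deviation from the average of all libraries, was 1.10 and 0.64 in UNX/DOCA vehicle replicates 3 and 4, and -0.25 and -0.02 in replicates 1 and 2. Sham vehicle lay between -0.42 and -0.05. The complement subunit gene C1qb averaged 63.3 ± 29.6 against 32.4 ± 4.40 CPM (adjusted p = 0.171) and Lgals3, which encodes galectin-3, 5.19 ± 2.76 against 2.06 ± 0.687 (adjusted p = 0.161). Complement and acute phase genes (15 genes, median 1.17, camera adjusted p = 0.00028, adjusted p = 0.484 with an estimated correlation) and class II antigen presentation genes (10 genes, median 0.79, camera adjusted p = 0.0036, adjusted p = 0.484 with an estimated correlation) were called higher. So were neutrophil genes (9 genes, median 2.47, camera adjusted p = 0.024, adjusted p = 0.703 with an estimated correlation) and chemokines and cytokines (22 genes, median 0.37, camera adjusted p = 0.026, adjusted p = 0.724 with an estimated correlation). Over all genes 0 of their members passed, and adjusted over the list alone 3 complement genes and 3 chemokine genes did. The alarmin Il33 averaged 15.1 ± 11.1 against 2.42 ± 0.451 CPM (adjusted p = 0.0998), and the chemokine Ccl9 26.9 ± 10.0 against 12.02 ± 2.11 (adjusted p = 0.130). The acute phase genes averaged 12.9 ± 11.005 against 3.14 ± 0.489 CPM for Lbp (adjusted p = 0.123) and 169 ± 114 against 38.3 ± 9.25 for Serpina3n (adjusted p = 0.136). The granulocyte receptor Csf3r averaged 16.8 ± 15.1 against 5.16 ± 1.72 (adjusted p = 0.279). Neutrophil scores were 3.63 and 2.53 in UNX/DOCA vehicle replicates 3 and 4, and -0.09 and -2.70 in replicates 1 and 2. Without UNX/DOCA vehicle replicate 3 the calls of neutrophils (camera adjusted p = 0.521), chemokines (0.518) and class II genes (0.0755) ended. The first 2 of these also ended without UNX/DOCA vehicle replicate 4 (0.119 for both) and Sham vehicle replicate 3 (0.0698 and 0.0951), and that of chemokines without Sham vehicle replicate 2 (0.0769). The macrophage, complement, protease, collagen processing, resident fibroblast, TGF-beta and fibrillar collagen calls ended when both replicates 3 and 4 were left out. Neutrophil genes were then called in the other direction (median -1.36, camera adjusted p = 0.0021, adjusted p = 0.785 with an estimated correlation). The fetal, proteoglycan, other collagen, ion channel, calcium handling and erythroid calls stayed, and were lost in that setting too with the correlation estimated (adjusted p = 0.314 to 0.634 with an estimated correlation).

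Erythroid genes had a median log2 fold change of -0.68 with 9 of 9 genes below 0 in UNX/DOCA vehicle (camera adjusted p = 5.9e-05, adjusted p = 0.484 with an estimated correlation). The globin gene Hbb-bt, whose reads cannot be told safely from those of its paralogs, averaged 23.8 ± 5.36 against 45.3 ± 2.53 CPM (adjusted p = 0.151). In this list 1 gene passed adjusted over the list alone against 0 over all genes. Smaller list differences were called for branched-chain and ketone catabolism (20 genes, median -0.14, camera adjusted p = 0.0036, adjusted p = 0.484 with an estimated correlation) and renin-angiotensin and natriuretic receptors (18 genes, median -0.19, camera adjusted p = 0.031, adjusted p = 0.432 with an estimated correlation). Respiratory complexes II to V were also called lower (36 genes, median -0.06, camera adjusted p = 0.046, adjusted p = 0.779 with an estimated correlation). Glucocorticoid and mineralocorticoid targets (20 genes, median 0.40, camera adjusted p = 0.013, adjusted p = 0.601 with an estimated correlation) and cytosolic ribosomal proteins (49 genes, median 0.07, camera adjusted p = 0.021, adjusted p = 0.764 with an estimated correlation), whose reads are shared with pseudogenes, were called higher. Adjusted over the list alone, 1 branched-chain gene and 1 gene of the receptor list, the neprilysin gene Mme (9.14 ± 1.97 against 16.6 ± 2.95 CPM, adjusted p = 0.0954), were lower and 3 corticoid targets were higher. The 11 genes of the zinc-dependent HDACs had log2 fold changes from -0.52 to 0.26, and 0 passed, the lowest being Hdac11 (6.69 ± 0.794 against 9.62 ± 1.22 CPM, adjusted p = 0.256). As a list they were not called (median -0.08, camera adjusted p = 0.163), but were called lower without UNX/DOCA vehicle replicate 3 (median -0.13, camera adjusted p = 0.0444), without replicates 3 and 4 (-0.18, 0.0432) and with no filter (-0.10, 0.0383). In the fit of all libraries the list had adjusted p = 0.613 with an estimated correlation, and without replicates 3 and 4 adjusted p = 0.634 with an estimated correlation. The ribosomal call ended without UNX/DOCA vehicle replicate 4 (0.181), Sham vehicle replicate 1 (0.123) and Sham vehicle replicate 2 (0.132). The corticoid call ended without UNX/DOCA vehicle replicate 3 (0.0775) and Sham vehicle replicate 2 (0.0775). The receptor call ended without UNX/DOCA vehicle replicate 1 (0.247), Sham vehicle replicate 3 (0.0506) and Sham vehicle replicate 4 (0.0551), and that of complexes II to V ended without UNX/DOCA vehicle replicates 1 (0.215) and 3 (0.123) and Sham vehicle replicate 3 (0.237), each left out alone.

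The genes with the smallest p in this comparison were fully separated between the groups and did not pass. The tendon transcription factor gene Scx averaged 8.21 ± 1.41 CPM in UNX/DOCA vehicle and 3.80 ± 0.455 in Sham vehicle. The leukotriene receptor Cysltr1 averaged 7.499 ± 1.41 against 2.60 ± 0.473, and the water channel Aqp8 9.72 ± 2.09 against 3.08 ± 1.18. On the other side, the inositol trisphosphate receptor Itpr2 averaged 26.7 ± 2.59 against 40.1 ± 1.67, Btbd11 1.79 ± 0.215 against 3.73 ± 0.615 and the collagen Col6a6 5.33 ± 0.466 against 9.88 ± 0.888. Their adjusted p was 0.0649 for each except Col6a6 at 0.0786. The count of 0 rested on the 12 libraries together: it became 380 (274 up, 106 down) without UNX/DOCA vehicle replicate 1 and 6 without UNX/DOCA vehicle replicate 2. It was 39 without UNX/DOCA ITF2357 replicate 1 and 11 without UNX/DOCA ITF2357 replicate 2, and stayed 0 without each of the others. In simulated data with independent genes and the same spread in each group, edgeR recovered 62% of genes given a 2-fold change and 29% of those given a 1.5-fold change. Real replicates differed most within UNX/DOCA vehicle, so these shares may not hold for the real libraries.

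**Figure D1:**
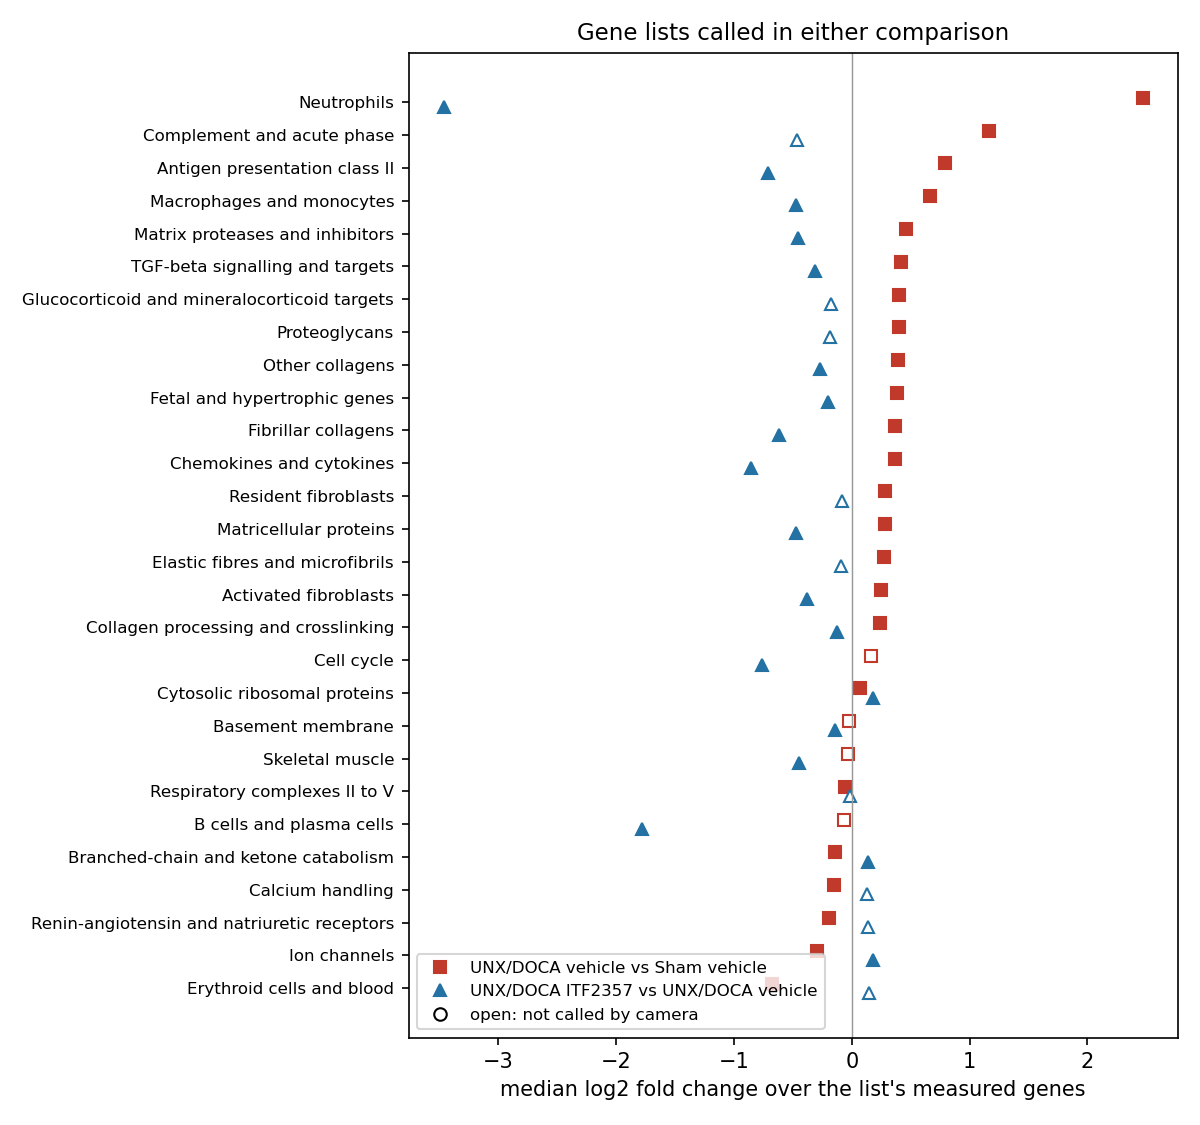
Median log2 fold change over the measured genes of each of the 28 gene lists called by camera in UNX/DOCA vehicle against Sham vehicle (squares) or in UNX/DOCA ITF2357 against UNX/DOCA vehicle (triangles), with open symbols where camera did not call the list. Neutrophil genes had the widest pair of medians, 2.47 and -3.46. Cell cycle (-0.76), B cell (-1.78), skeletal muscle type (-0.44) and basement membrane genes (-0.14) were called in the second comparison alone. None of the calls held with an estimated correlation.

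The second comparison, UNX/DOCA ITF2357 against UNX/DOCA vehicle, asked what the HDAC inhibitor changed in operated mice. As lists, camera called cell cycle genes, B cell genes, fibrillar collagens and genes of skeletal muscle type lower with ITF2357, and ribosomal protein and ion channel genes higher. None of these calls held with the correlation estimated (adjusted p = 0.141 to 0.542 with an estimated correlation). edgeR called 153 of 16981 genes, of which 78 rose and 75 fell, with a median absolute log2 fold change of 0.78 and 53 genes beyond 2-fold. The count was 5 with only the 2 groups compared, 68 with a replicate block and 10 in a test against a 1.2-fold change. An unadjusted p under 0.05 was found for 3141 genes, where 849 would be expected by chance. In fits of the 2 groups alone the real groups had 2440 such genes, and divisions across the groups had up to 1696. DESeq2 called 928 genes and limma-voom 251, and in simulated data 26 of 136 calls of DESeq2 and 4 of 78 of edgeR were false. Ndrg4, an N-myc downstream regulated gene of heart and brain, rose from 63.0 ± 6.30 to 164 ± 23.4 CPM (2.60-fold, adjusted p = 0.0010). Top2a, the DNA topoisomerase of dividing cells, fell from 3.56 ± 1.99 to 0.554 ± 0.265 CPM (adjusted p = 0.0204). Both held in all 4 against 4 libraries, which the naming rule requires. With upper-quartile scaling, the split was 108 up and 65 down. With the clock covariate 62 genes were called, 51 of them among the 153, and 12 with UNX/DOCA vehicle replicates 3 and 4 left out. The median absolute log2 fold change of the 153 was 0.82 with a median SE of 0.165 with that covariate, against 0.78 and 0.149 without it. All 153 kept their sign, which is likely for genes chosen by their call.

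The cell cycle list had a median log2 fold change of -0.76 with 25 of 26 genes below 0 (camera adjusted p = 7.3e-16, adjusted p = 0.267 with an estimated correlation, fry adjusted p = 0.0340). Of its genes 4 fell over all genes and 13 adjusted over the list alone. Beside Top2a these were the cyclin gene Ccnb2 (log2 fold change -1.90 ± 0.27, adjusted p = 0.0110), the spindle checkpoint kinase gene Bub1 (-2.42 ± 0.49, adjusted p = 0.0434) and the ubiquitin-conjugating enzyme gene Ube2c (-1.15 ± 0.24, adjusted p = 0.0478). These genes were at the low end of expression: Ccnb2 averaged 0.192 ± 0.0468 CPM with ITF2357 and 0.724 ± 0.148 without. The list stayed called when UNX/DOCA vehicle replicates 3 and 4 were left out (median -1.03). B cell and plasma cell genes had a median of -1.78 with 7 of 7 below 0 (camera adjusted p = 5.0e-07, adjusted p = 0.267 with an estimated correlation, fry adjusted p = 0.0340). Of these 3 fell over all genes and 5 adjusted over the list alone, among them Cd79b (-1.78 ± 0.36, adjusted p = 0.0432), a part of the B cell receptor, which averaged under 1 CPM in each group. Skeletal muscle type genes had a median of -0.44 over 9 genes (camera adjusted p = 0.00040, adjusted p = 0.141 with an estimated correlation, fry adjusted p = 0.0041), with 3 fallen over all genes and 3 adjusted over the list alone. Casq1, the calsequestrin of skeletal muscle, fell from 22.6 ± 3.71 to 9.84 ± 1.79 CPM (adjusted p = 0.0196). Myl1 fell from 12.6 ± 2.49 to 6.16 ± 1.22 (adjusted p = 0.0315) and Mybpc2 from 50.9 ± 8.32 to 22.4 ± 7.53 (adjusted p = 0.0382). Acta1 averaged 941 ± 508 with ITF2357 against 2460 ± 496 CPM and did not pass (adjusted p = 0.136).

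Of the 11 matrix, fibroblast and TGF-beta lists, camera called 8 lower with ITF2357 (adjusted p = 0.323 to 0.591 with an estimated correlation). Elastic fibre genes (median -0.09, camera adjusted p = 0.113), proteoglycans (-0.18, 0.230) and resident fibroblast genes (-0.08, 0.476) were not called. Fibrillar collagens had a median log2 fold change of -0.62 with 7 of 7 genes below 0 (camera adjusted p = 2.1e-06, adjusted p = 0.323 with an estimated correlation). Of these 6 fell adjusted over the list alone and 0 over all genes. Col3a1 averaged 117 ± 24.4 against 234 ± 70.4 CPM (adjusted p = 0.0584), and Col1a1 44.2 ± 14.02 against 77.7 ± 31.5 (adjusted p = 0.138). Col5a1 averaged 24.8 ± 3.35 against 39.5 ± 12.8 (adjusted p = 0.0915) and Col5a2 28.6 ± 6.25 against 42.0 ± 6.90 (adjusted p = 0.109). Basement membrane genes (20 genes, median -0.14, camera adjusted p = 0.015, adjusted p = 0.542 with an estimated correlation) held 2 genes that fell over all genes, and 4 that fell and 1 that rose adjusted over the list alone. Those 2 were the type IV collagens Col4a1, from 528 ± 66.3 to 300 ± 74.8 CPM (adjusted p = 0.0395), and Col4a2, from 396 ± 78.2 to 236 ± 48.0 (adjusted p = 0.0496). Among other collagens (16 genes, median -0.27, camera adjusted p = 0.029, adjusted p = 0.542 with an estimated correlation) Col6a2 fell, from 82.3 ± 20.8 to 47.6 ± 4.99 CPM (adjusted p = 0.0349), as the 1 call over all genes, against 4 fallen and 1 risen adjusted over the list alone. Among collagen processing genes (25 genes, median -0.13, camera adjusted p = 0.00051, adjusted p = 0.542 with an estimated correlation) 2 fell over all genes and 4 adjusted over the list alone. The 2 were the lysyl oxidase-like genes Loxl2, from 26.6 ± 5.01 to 13.5 ± 2.67 CPM (adjusted p = 0.0349), and Loxl1, from 26.5 ± 5.20 to 16.7 ± 0.956 (adjusted p = 0.0496). Matricellular proteins (19 genes, median -0.47, camera adjusted p = 0.029, adjusted p = 0.591 with an estimated correlation) were lower as a list, but the 1 gene called, over all genes and adjusted over the list alone, was Thbs2, a thrombospondin, which rose from 14.8 ± 1.97 to 30.9 ± 6.88 CPM (adjusted p = 0.0349). Postn (49.99 ± 17.4 against 76.5 ± 18.8 CPM, adjusted p = 0.316) and Fn1 (44.4 ± 9.37 against 62.5 ± 28.6, adjusted p = 0.322) did not pass. Matrix proteases (26 genes, median -0.45, camera adjusted p = 0.00057), TGF-beta targets (20 genes, median -0.31, camera adjusted p = 0.0083) and activated fibroblast genes (18 genes, median -0.38, camera adjusted p = 0.025) were called lower, each with adjusted p = 0.542 with an estimated correlation. Adjusted over the list alone, 3, 1 and 3 of their genes fell and 1 activated fibroblast gene rose, against 0 over all genes. With UNX/DOCA vehicle replicates 3 and 4 both left out, the medians of proteases (0.00865, camera adjusted p = 0.243) and other collagens (0.010, camera adjusted p = 0.202) lay above 0 and 7 of these 8 calls ended, while that of fibrillar collagens stayed. Without UNX/DOCA vehicle replicate 3 the calls of TGF-beta targets (0.136), basement membrane (0.0538), activated fibroblasts (0.269), matricellular proteins (0.422) and other collagens (0.204) ended. The basement membrane call also ended without UNX/DOCA ITF2357 replicate 4 (0.0746). So did activated fibroblasts without that library (0.0515) or UNX/DOCA vehicle replicate 1 (0.0523), and, without UNX/DOCA ITF2357 replicate 1, matricellular proteins (0.164) and other collagens (0.136).

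Of the 5 immune lists called higher in UNX/DOCA vehicle, 4 were called lower with ITF2357 (adjusted p = 0.542 with an estimated correlation for each), and UNX/DOCA vehicle replicates 3 and 4 carried this too. Complement and acute phase genes were not called (median -0.46, camera adjusted p = 0.121). Neutrophil genes had a median log2 fold change of -3.46 (9 genes, camera adjusted p = 0.00063, adjusted p = 0.542 with an estimated correlation), with 9 lower adjusted over the list alone and 0 over all genes. The granule gene S100a8 averaged 2.60 ± 1.64 against 49.5 ± 73.6 CPM (adjusted p = 0.141) and Retnlg 1.00 ± 0.495 against 16.96 ± 21.97 (adjusted p = 0.136). Macrophages (22 genes, median -0.48, camera adjusted p = 0.00019), chemokines (22 genes, median -0.85, camera adjusted p = 0.00019) and class II genes (10 genes, median -0.71, camera adjusted p = 0.012) were called lower, each with adjusted p = 0.542 with an estimated correlation. They had 0 calls over all genes, and 0, 3 and 0 adjusted over the list alone. The lysozyme gene Lyz2 averaged 37.3 ± 5.44 against 69.7 ± 32.1 CPM (adjusted p = 0.142) and the chemokine Cxcl2 0.252 ± 0.240 against 2.88 ± 2.36 (adjusted p = 0.117). Without UNX/DOCA vehicle replicate 3 the camera calls of neutrophils (adjusted p = 0.0551), macrophages (0.0604), chemokines (0.0519) and class II genes (0.215) ended. With replicates 3 and 4 both left out the macrophage median was 0.10 and the neutrophil median 0.23.

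**Figure D2:**
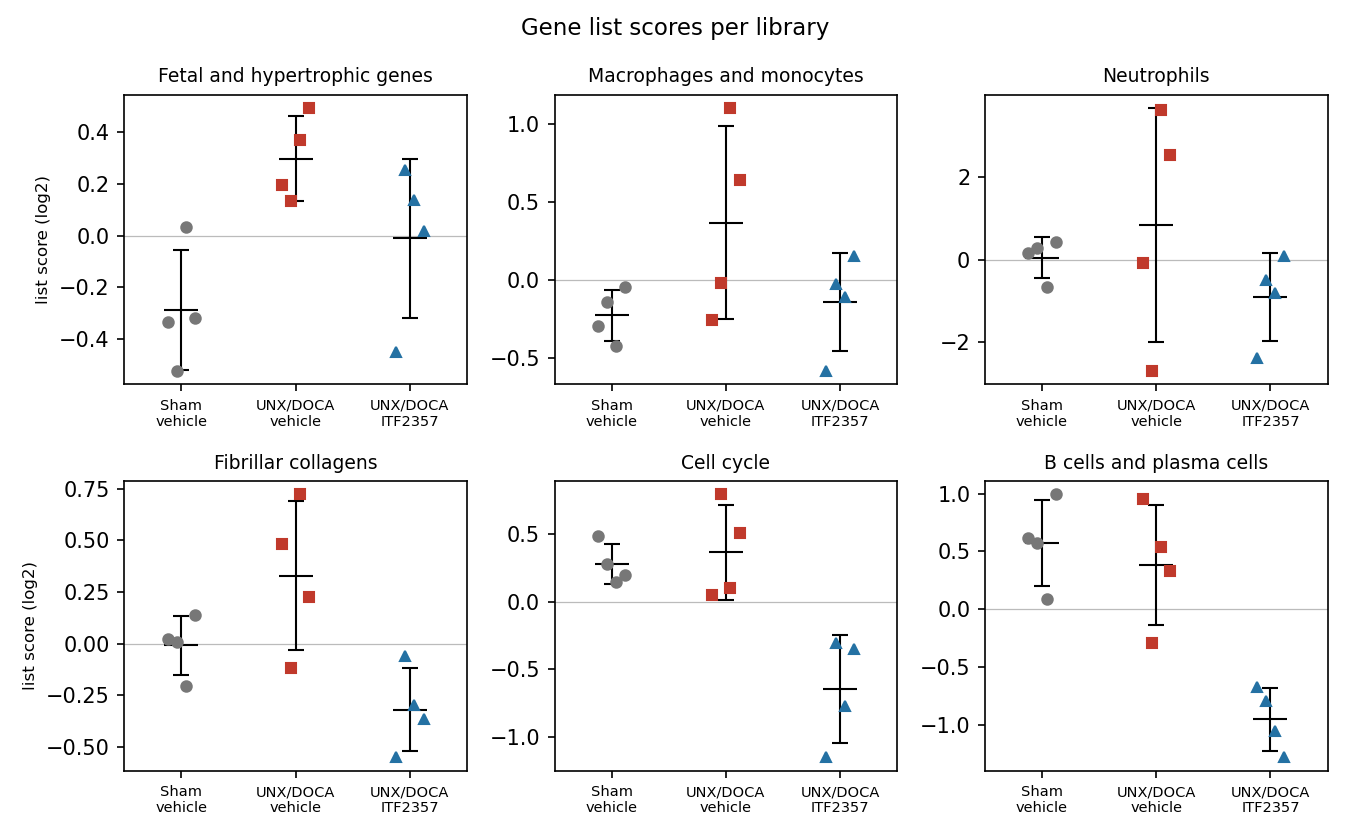
Score of 6 gene lists in each of the 12 libraries (mean log2 deviation of the list's genes from the average of all libraries), with points for libraries, bars for the group mean and whiskers for the SD (n = 4). The 4 ITF2357 libraries lie below all others for cell cycle and B cell genes, and the neutrophil score of UNX/DOCA vehicle runs from -2.70 to 3.63.

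Cytosolic ribosomal protein genes were higher with ITF2357 by a small amount, with a median log2 fold change of 0.18 and 48 of 49 genes above 0 (camera adjusted p = 5.2e-10, adjusted p = 0.542 with an estimated correlation). Of these 30 rose adjusted over the list alone and 0 over all genes, with Rps16 at 140 ± 9.10 against 115 ± 8.88 CPM (adjusted p = 0.0769), and reads of this family are shared with pseudogenes. In the same comparison mitochondrially encoded mRNAs had a median of 0.13 with 13 of 13 above 0, and immediate early genes a median of -0.34 with 16 of 20 below 0, and neither was called (camera adjusted p = 0.0634 for both). Ion channel genes had a median of 0.18 over 27 genes (camera adjusted p = 0.00057, adjusted p = 0.408 with an estimated correlation), with 2 risen over all genes and 2 adjusted over the list alone. These were the potassium channel subunit Kcnv2, from 8.92 ± 2.09 to 22.1 ± 8.24 CPM (adjusted p = 0.0349), and the pacemaker channel Hcn2, from 33.4 ± 3.46 to 58.9 ± 11.3 (adjusted p = 0.0385). Branched-chain and ketone catabolism genes had a median of 0.13 over 20 genes (camera adjusted p = 0.0012, adjusted p = 0.542 with an estimated correlation), with 7 higher adjusted over the list alone and 0 over all genes. The aminotransferase gene Bcat2 averaged 191 ± 9.26 against 157 ± 6.42 CPM (adjusted p = 0.0633). Fetal and hypertrophic genes had a median of -0.20 over 18 genes (camera adjusted p = 0.018, adjusted p = 0.542 with an estimated correlation), and this call ended without UNX/DOCA ITF2357 replicate 1 (camera adjusted p = 0.295). Rcan1 fell over all genes, from 234 ± 77.4 to 108 ± 10.3 CPM (adjusted p = 0.0324), and 2 genes adjusted over the list alone. Nppa lay on the other side of 0, with 563 ± 310 against 283 ± 45.8 CPM (adjusted p = 0.201), as did Myh7 (492 ± 156 against 363 ± 55.4 CPM, adjusted p = 0.302). Nppb (-0.20 ± 0.34, adjusted p = 0.796), Myh6 (0.08 ± 0.11, adjusted p = 0.754) and Atp2a2 (0.16 ± 0.06, adjusted p = 0.196) did not pass. The genes of the drug's targets had log2 fold changes from -0.39 to 0.27 over 11 HDACs, with 0 passed (smallest adjusted p = 0.303, Hdac2). As a list they were not called (median -0.06, camera adjusted p = 0.860). A list of 19 HDAC inhibitor response genes from cell culture work, drawn from general knowledge, was not called either (median -0.02, camera adjusted p = 0.860, with a median of 0.01 under upper-quartile scaling). Camera asks for a shift in one direction, so genes of this list that moved both ways would not show. At an unadjusted p under 0.05, 4 of the 19 were higher and 3 lower, and 0 passed adjusted over the list alone. Over all genes, 3141 of 16981 had such a p. The smallest p of the list was that of the cyclin gene Ccnd1 (17.7 ± 2.24 against 23.9 ± 4.63 CPM, adjusted p = 0.106).

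The largest changes with ITF2357 were ranked among called, fully separated genes with at least 1 CPM in the higher group and an approved symbol. They were at low to moderate expression. Upward these were Fbxo44 (2.17 ± 0.338 against 0.540 ± 0.1102 CPM, 4.02-fold, adjusted p = 0.0013), a substrate adaptor of a ubiquitin ligase, the acyl-CoA synthetase gene Acss3 (3.91-fold, adjusted p = 0.0364) and the receptor chaperone gene Tmem35a (3.52-fold, adjusted p = 0.0010). They were followed by the co-receptor gene Ramp1 (3.18-fold, adjusted p = 0.0254), the midkine gene Mdk (2.72-fold, adjusted p = 0.0407), Zfp286 (2.6999-fold, adjusted p = 0.0300), Agbl2 (2.65-fold, adjusted p = 0.0496) and Ndrg4. Downward, besides Top2a, were the immunoglobulin gene Ighd (log2 fold change -3.03 ± 0.47, adjusted p = 0.0196, and -2.39 with the clock covariate, adjusted p = 0.0294), Iqgap3 (-2.01 ± 0.38, adjusted p = 0.0364), and the spindle gene Spag5 (-1.80 ± 0.33, adjusted p = 0.0349). The others were Zp2 (-1.77 ± 0.34, adjusted p = 0.0378), Rtl3 (-1.67 ± 0.21, adjusted p = 0.0057), Glipr2 (-1.31 ± 0.25, adjusted p = 0.0364) and the myosin light chain pseudogene Mylf-ps (-1.25 ± 0.22, adjusted p = 0.0300), whose reads may belong to Mylpf relatives. Of the 32 called genes named for this comparison, 4 stayed called without each of the 12 libraries in turn: Fbxo44, Tmem35a, Ndrg4 and Rtl3. Of the 32, 5 stayed without UNX/DOCA ITF2357 replicate 1, 25 without replicate 2, 7 without replicate 3 and 6 without replicate 4 of that group. The numbers were 26, 29, 13 and 6 without UNX/DOCA vehicle replicates 1, 2, 3 and 4, and 14, 12, 18 and 12 without Sham vehicle replicates 1, 2, 3 and 4. The total of 153 became 243, 234, 68 and 18 without UNX/DOCA vehicle replicates 1 to 4. It became 14, 151, 27 and 26 without UNX/DOCA ITF2357 replicates 1 to 4, and 66, 49, 71 and 47 without Sham vehicle replicates 1 to 4. In simulated data of the same kind edgeR recovered 52% of genes given a 2-fold change and 22% of those given a 1.5-fold change in this comparison. Both simulations used the same means and spreads, so 62% and 52% do not rank the comparisons.

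**Figure D3:**
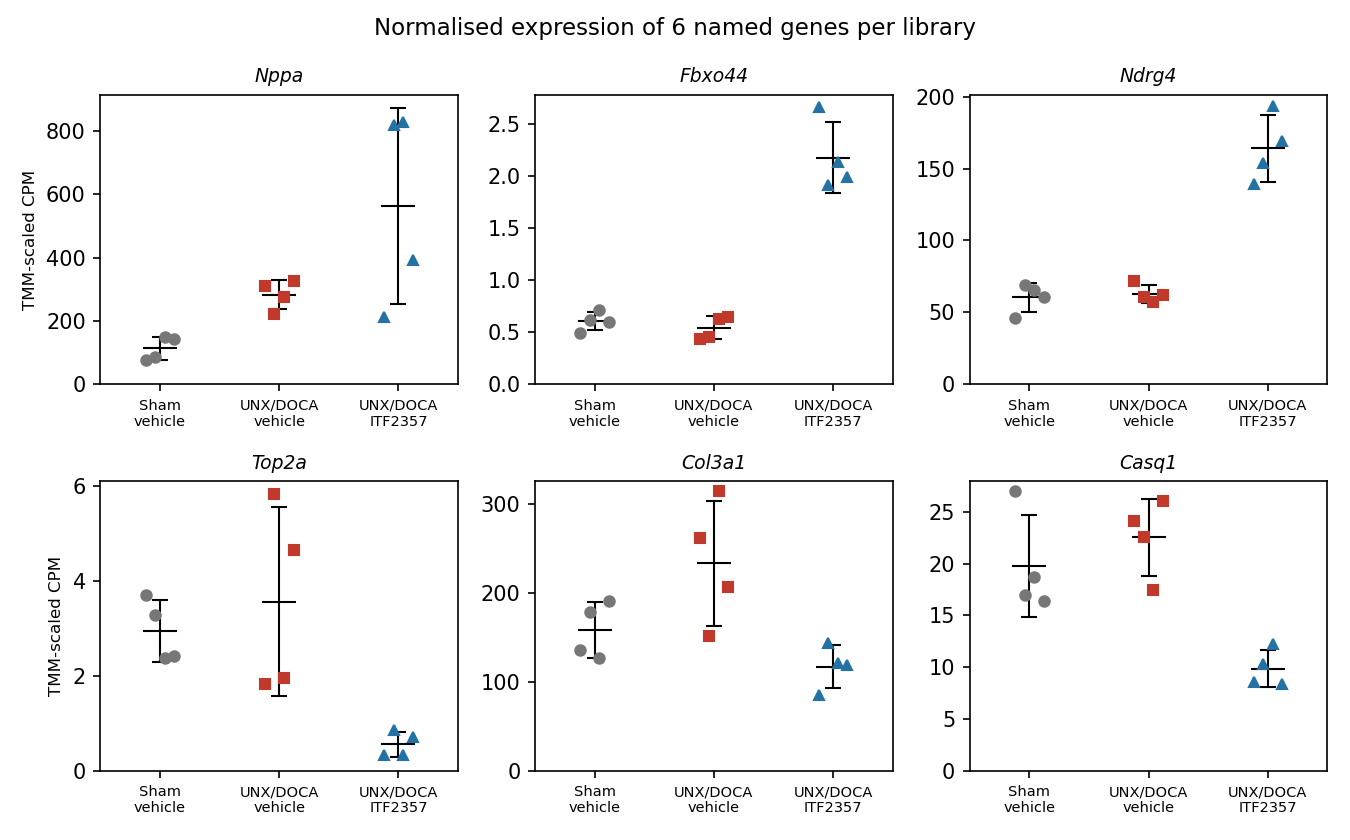
TMM-scaled CPM of 6 named genes in each of the 12 libraries on axes that start at 0, with points for libraries, bars for the group mean and whiskers for the SD (n = 4). Ndrg4 and Fbxo44 separate the ITF2357 libraries from both other groups, while Nppa runs from 213 to 829 CPM among the ITF2357 libraries.

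The third comparison, UNX/DOCA ITF2357 against Sham vehicle, describes treated mice relative to mice with a sham operation and no drug, so that both effects are in it. As lists, camera called cell cycle and B cell genes lower and ribosomal protein genes higher than in Sham vehicle. None of these calls held with the correlation estimated (adjusted p = 0.213 to 0.906 with an estimated correlation). Nppa rose 4.95-fold, from 114 ± 36.9 to 563 ± 310 CPM (adjusted p = 0.0269), and Myh7 averaged 492 ± 156 against 272 ± 57.4 CPM without passing (adjusted p = 0.0653). edgeR called 298 genes, 155 up and 143 down, 79 of them beyond 2-fold (3413 with an unadjusted p under 0.05). DESeq2 called 1180 and limma-voom 1506. The split was 214 up and 89 down with upper-quartile scaling and 172 up and 98 down with library totals. With the clock covariate, the first component of a list of clock genes, 2 genes were called. That component was above 0 in 4 of 4 ITF2357 and 1 of 4 Sham vehicle libraries. Over the 298 genes the median absolute log2 fold change was 0.61 with a median SE of 0.121 without the covariate, and 0.55 with a median SE of 0.148 with it. All 298 kept their sign, which is likely for genes chosen by their call.

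Cytosolic ribosomal protein genes had a median log2 fold change of 0.25 with 49 of 49 above 0, 6 risen over all genes and 44 adjusted over the list alone (camera adjusted p = 2.1e-17, adjusted p = 0.906 with an estimated correlation, fry adjusted p = 0.0275). Cell cycle genes had a median of -0.99 over 26 genes, 3 fallen over all genes and 14 adjusted over the list alone (camera adjusted p = 4.7e-13, adjusted p = 0.413 with an estimated correlation, fry adjusted p = 0.0355). B cell genes had a median of -2.08 over 7 genes, 3 fallen over all genes and 5 adjusted over the list alone (camera adjusted p = 4.9e-09, adjusted p = 0.213 with an estimated correlation, fry adjusted p = 0.0153). Skeletal muscle type genes had a median of -0.58 over 9 genes (camera adjusted p = 0.0091, adjusted p = 0.213 with an estimated correlation, fry adjusted p = 0.0153), with 2 fallen over all genes, and 4 fallen and 1 risen adjusted over the list alone. Erythroid genes (9 genes, median -0.52, camera adjusted p = 0.0045) and immediate early genes (20 genes, median -0.64, camera adjusted p = 0.0084) were called lower, each with adjusted p = 0.906 with an estimated correlation, with 0 genes over all genes and 1 fallen in each adjusted over the list alone. The immediate early call ended without UNX/DOCA ITF2357 replicate 1 (0.164), UNX/DOCA ITF2357 replicate 3 (0.132) and Sham vehicle replicate 3 (0.0520). Macrophage genes were not called (median 0.11, adjusted p = 0.937 with an estimated correlation), but were called higher with the immediate early covariate (median 0.33, camera adjusted p = 0.0130). Fibrillar collagens were not called either (median -0.43, adjusted p = 0.906 with an estimated correlation). They were called lower without UNX/DOCA vehicle replicate 2 (camera adjusted p = 0.0408), UNX/DOCA vehicle replicate 3 (0.0382), both UNX/DOCA vehicle replicates 3 and 4 (0.0415) or UNX/DOCA ITF2357 replicate 2 (0.0153), and with no filter (0.0470). The HDAC list was not called (median -0.05, camera adjusted p = 0.235, adjusted p = 0.906 with an estimated correlation) except with no filter (median -0.07, camera adjusted p = 0.0470), and its genes ran from -0.52 to 0.16 with 0 passed (smallest adjusted p = 0.145, Hdac5). For lists against Sham vehicle the correlation was estimated only in the fit of all libraries.

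The largest changes against Sham vehicle were ranked among called, fully separated genes with at least 1 CPM in the higher group and an approved symbol. Besides Nppa, the largest rises against Sham vehicle were those of Psca (5.83-fold, adjusted p = 0.0384), Fbxo44 (3.57-fold, adjusted p = 0.0032), Dkk3 (3.40-fold, adjusted p = 0.0259) and Mdk (3.08-fold, adjusted p = 0.0259). The largest falls were those of Ighd (log2 fold change -3.09 ± 0.47, adjusted p = 0.0133), Top2a (-2.39 ± 0.44, adjusted p = 0.0269), Shisa6 (-1.94 ± 0.39, adjusted p = 0.0344), the Nogo receptor gene Rtn4r (-1.93 ± 0.38, adjusted p = 0.0344) and the chemokine Ccl24 (-1.76 ± 0.23, adjusted p = 0.0065). Col3a1 (-0.43 ± 0.22, adjusted p = 0.296), Col1a1 (-0.44 ± 0.26, adjusted p = 0.371), and Postn (0.37 ± 0.31, adjusted p = 0.546) did not pass, nor did Acta1 (-0.34 ± 0.43, adjusted p = 0.700), Nppb (-0.37 ± 0.34, adjusted p = 0.588), Myh6 (-0.15 ± 0.11, adjusted p = 0.481) and Atp2a2 (-0.12 ± 0.06, adjusted p = 0.298). Fn1 averaged 44.4 CPM in each group. Without UNX/DOCA ITF2357 replicate 2 the log2 fold change of Psca was 1.94 in place of 2.54, and its call ended (adjusted p = 0.0611). With the clock covariate Ighd (-2.30, adjusted p = 0.0783) and Rtn4r (-1.12, adjusted p = 0.181) were nearer to 0 and did not pass. Fbxo44 and Ccl24 stayed called without each library in turn. Of the 10 genes called, 2, 3 and 4 stayed without Sham vehicle replicates 1, 2 and 4. The number was 4 without UNX/DOCA ITF2357 replicate 3, 6 without UNX/DOCA ITF2357 replicate 4, 7 without UNX/DOCA ITF2357 replicate 2 or UNX/DOCA vehicle replicate 4, and 9 or 10 without each of the others. The total of 298 became 17, 23 and 23 without Sham vehicle replicates 1, 2 and 4. It became 153, 55 and 72 without UNX/DOCA ITF2357 replicates 2, 3 and 4, and 616 and 120 without UNX/DOCA vehicle replicates 3 and 4.

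Whether ITF2357 moved genes back toward Sham vehicle was read across genes. The log2 fold changes of the first and second comparisons correlated negatively over the 16981 genes (Pearson r = -0.51, Spearman rho = -0.43), and genes are not independent replicates. Both comparisons use the same UNX/DOCA vehicle libraries, which alone gives a negative correlation. In 20 simulated data sets with no change between groups r averaged -0.50 (-0.52 to -0.48). The covariance was -0.0864 in the data and -0.0412 in the simulations. The simulations gave a gene the same spread in each group. The largest chi-square per degree of freedom between replicates was 57.3 in UNX/DOCA vehicle, 33.1 in UNX/DOCA ITF2357 and 26.2 in Sham vehicle. A wider spread of the shared libraries gives a more negative covariance, so the gap cannot be read as an excess over sharing. With the 4 UNX/DOCA vehicle libraries divided 2 and 2 between the comparisons, r averaged -0.15 and the covariance -0.0294, from -0.0587 to 0.0082 over 6 assignments. Because no gene was called by UNX/DOCA with edgeR, 0 genes were called in opposite directions by the operation and by ITF2357. The count was 136 with DESeq2 and 46 with limma-voom, and with edgeR 72, 4 and 3 without UNX/DOCA vehicle replicate 1, UNX/DOCA vehicle replicate 2 and UNX/DOCA ITF2357 replicate 2. At unadjusted p under 0.05, 70 of the 153 genes called with ITF2357 also differed between UNX/DOCA and Sham vehicle, and 69 of these with the opposite sign, 98.6%. The shared libraries alone give such a share. It averaged 99.5% in the simulated data with no change, over the 153 genes with the smallest p in the second comparison. With the libraries divided between the comparisons it was 71.1% (56.9% to 88.9% over the 6 assignments), and independent lists would give 49.8%. The part of the UNX/DOCA change left under ITF2357 could not be taken over called genes, of which there were 0. Over the 2699 genes with an unadjusted p under 0.05 the slope of the third comparison on the first was 0.493. The slope was 0.329 to 0.611 with 1 library left out. Both comparisons subtract the same Sham vehicle libraries, which alone gives a slope above 0 without any UNX/DOCA change. The simulated data with no change were not used for this slope, so it cannot measure the part left under ITF2357. With genes chosen from 2 UNX/DOCA vehicle libraries, the slope was 0.405 for ITF2357 (0.256 to 0.587) and 0.590 for the 2 held-out UNX/DOCA vehicle libraries (0.242 to 0.822). Both of these slopes also rest on the same Sham vehicle libraries. The ranges overlapped, while within an assignment the slope was lower for ITF2357 in 5 of 6, and the assignments share libraries.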

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

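Chosen only after the result was seen were the test of the macrophage list against Sham, the test of clock phase for the division that crosses the groups, the count of gene lists in the test for a swap, the demand that both swap tests or all assignments of a division go one way, and the choice of covariates and of UNX/DOCA vehicle replicates 3 and 4 to leave out.

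A library stood far from the other 3 of its group (by Dixon's ratio of the gap to the nearest library over the group's range) in 17 of 276 groups of 4 values, 6.16%, where chance gives about 1 in 20. In UNX/DOCA vehicle these were replicate 3 for Abcc9 (241 CPM against 321 to 331), Acss3 (0.125 CPM against 0.360 to 0.405) and the calcium handling score (-0.22 against -0.04 to 0.00), replicate 2 for Col4a1 (429 CPM against 554 to 571), replicate 1 for Hbb-bt (15.9 CPM against 25.4 to 27.3) and replicate 4 for Ramp1 (1.87 CPM against 1.38 to 1.45). In UNX/DOCA ITF2357 replicate 2 stood apart for Fn1 (58.4 CPM against 38.9 to 40.7), Hdac2 (45.6 CPM against 54.2 to 55.0) and the basement membrane score (0.16 against -0.17 to -0.13). Replicate 1 of that group did for Tmem35a (9.61 CPM against 6.69 to 6.96), the collagen processing score (-0.20 against -0.02 to 0.01) and the erythroid score (0.39 against -0.49 to -0.36). In Sham vehicle replicate 4 did for Lgals3 (3.08 CPM against 1.65 to 1.86), Postn (65.4 CPM against 27.9 to 31.7) and Serpina3n (52.2 CPM against 33.0 to 34.3), replicate 1 for Hdac5 (96.7 CPM against 83.0 to 85.0) and replicate 2 for the total count (34.9 M counts against 25.3 to 26.9). No library held more than 3 of the 17.

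The first pattern weighed is that log2 fold changes with ITF2357 ran opposite to those of UNX/DOCA across genes. Sharing the UNX/DOCA vehicle libraries alone gave a covariance of -0.0412 in simulations against -0.0864 in the data. The simulations gave each group the same spread, while the largest difference between replicates lay in UNX/DOCA vehicle. The gap therefore cannot be read as an excess over sharing. With the UNX/DOCA vehicle libraries divided between the contrasts 5 of 6 assignments stayed below 0, so sharing as the whole source can neither be excluded nor shown. The assignments below -0.03 were those with replicates 3 and 4 on opposite sides. With both left out and replicates 1 and 2 divided the covariance was -0.0093 in 1 assignment and 0.0583 in the other (mean 0.0245), which leaves neutrophil and macrophage content of replicates 3 and 4 open as a source. With clock phase in the model 4 of 6 assignments were below 0, which leaves clock phase open, and a true return toward Sham with ITF2357 stays open too.

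The second pattern is that cell cycle genes were lower with ITF2357 (median log2 fold change -0.76). With clock phase in the model the median was -0.84 (camera adjusted p = 1.9e-16). With the immune-rich UNX/DOCA vehicle replicates 3 and 4 left out it was -1.03 (camera adjusted p = 4.9e-21). The lower median thus did not rest on these 2 libraries and was not taken up by the clock component. That component was positive in every UNX/DOCA ITF2357 library and associated with few genes outside the clock list, so clock phase is not excluded. Macrophage genes were lower than in UNX/DOCA vehicle too (median -0.48, camera adjusted p = 0.00019, adjusted p = 0.542 with an estimated correlation), as fewer macrophages would give. With UNX/DOCA vehicle replicates 3 and 4 left out the macrophage median was 0.10. Fewer macrophages would also lower macrophage genes against Sham, where cell cycle genes had a median of -0.99. The macrophage median there was 0.11 ± 0.375 (SD of 22 genes, which are not independent), and -0.23 with the clock covariate. Fewer macrophages are thus not excluded. Fewer dividing cells under the HDAC inhibitor may be the reason, as a hypothesis found on these data and not tested. B cell genes were lower with ITF2357 too (median -1.78 against UNX/DOCA vehicle and -2.08 against Sham vehicle). A loss of cell types other than macrophages was not tested. The camera call of cell cycle genes was lost with an estimated correlation (adjusted p = 0.267), and which cells divide cannot be read from bulk tissue.

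The third pattern is that a division of Sham and UNX/DOCA vehicle libraries across the groups, UNX/DOCA vehicle replicate 1 with Sham vehicle replicates 1, 2 and 4 against the rest, called 121 genes where the real groups called 0, which points to a structure of the samples. The clock component separated those sides fully (-4.48 to -1.40 against -0.75 to 2.17, exact permutation p = 0.0286, the smallest possible), with 2 of 18 clock genes called, Ciart and Dbp. That p takes the division as fixed in advance, but it was picked from 35 for its count of genes. As a covariate within groups the component was associated with 6 genes, 1 of them outside its list. The immediate early score (exact p = 1) and total counts (exact p = 0.657) overlapped between the sides. With 4 libraries on each side such an overlap cannot exclude tissue handling or depth. Time of tissue collection, not given in the sources used here, could give such a clock difference. A swap of labels between UNX/DOCA vehicle replicate 1 and Sham vehicle replicate 3 would give this division too. On a scale from the Sham to the UNX/DOCA mean of the other libraries these lay at 0.329 and 0.292, a difference of 0.0372 that decides nothing, and 17 of the 19 gene lists called without them put replicate 1 of UNX/DOCA vehicle further in the direction of the call, but these lists are not independent and the targets of glucocorticoids and mineralocorticoids (-0.12 against 0.31) and ribosomal proteins went the other way, so a swap stays open.

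For UNX/DOCA vehicle against Sham vehicle, with 0 genes called, 35 of the 35 divisions of the 8 libraries into 4 and 4 must call as many, so this count cannot decide on chance, with 121 as the highest other. At an unadjusted p under 0.05 the real groups had 2558 genes in that 2-group fit, the most of the 35, and that other division had 2538. For UNX/DOCA ITF2357 against UNX/DOCA vehicle, 1 of 35 divisions, the real one with 5 genes in the 2-group fit, called as many, with 1 gene as the highest other. For UNX/DOCA ITF2357 against Sham vehicle, 1 of 35 did, the real one with 475 genes, with 120 as the highest other (UNX/DOCA ITF2357 replicate 1 with Sham vehicle replicates 1, 2 and 4). In both this division and the one with 121 genes, Sham vehicle replicate 3 lay apart from Sham vehicle replicates 1, 2 and 4. The clock component also separated the sides of the division with 120 genes (-3.34 to 0.68 against 1.37 to 2.80). Its cause was not tested. In the last 2 comparisons the real division thus called the most genes, which is the furthest that 35 divisions can go. Chance is not excluded by this, since divisions across the groups called 121 genes in the first comparison and 120 in the third. The counts of 153 and 298 from the fit of 12 libraries were not tested this way.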

How the results depend on the processing

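Chosen after the data were seen were the settings with the clock covariate, the immediate early covariate, UNX/DOCA vehicle replicates 3 and 4 left out, and the slope over genes with an unadjusted p under 0.05. Where a value moved, the cause was not tested unless the setting itself shows it.

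Scaling with RLE, library totals and a stricter filter kept each count of genes within 1.5 times its value. UNX/DOCA vehicle against Sham vehicle, 0 genes in the report, gave 7 genes with upper-quartile scaling, 210 with no filter, 593 with DESeq2, 521 with limma-voom, 31 with a replicate block, 509 with the immediate early covariate and 1 with UNX/DOCA vehicle replicates 3 and 4 left out. Leaving out 1 library gave 0 to 380. UNX/DOCA ITF2357 against UNX/DOCA vehicle, 153 in the report, gave 352 with no filter, 928 with DESeq2, 251 with limma-voom, 5 with only the 2 groups compared, 68 with a replicate block, 10 with glmTreat (a stricter question), 62 with the clock covariate, 88 with the immediate early covariate and 12 with replicates 3 and 4 left out. Leaving out 1 library gave 14 to 243. UNX/DOCA ITF2357 against Sham vehicle, 298 in the report, gave 1180 with DESeq2, 1506 with limma-voom, 475 with only the 2 groups compared, 192 with a replicate block, 18 with glmTreat, 2 with the clock covariate and 481 with UNX/DOCA vehicle replicates 3 and 4 left out. Leaving out 1 library gave 17 to 616.

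Genes called in opposite directions by UNX/DOCA and ITF2357, 0 in the report, numbered 2 with upper-quartile scaling, 48 with no filter, 136 with DESeq2, 46 with limma-voom, 5 with a replicate block, 21 with the immediate early covariate, 1 with replicates 3 and 4 left out and 0 to 72 with 1 library left out. The correlation across genes, -0.51 in the report, was -0.43 with the immediate early covariate, -0.40 with replicates 3 and 4 left out and -0.62 to -0.38 with 1 library left out, and moved by less than its spread of 0.0654 in the other settings. The slope of the third comparison on the first, which shared Sham vehicle libraries alone put above 0, was 0.493 in the report. It was 0.634 with the immediate early covariate and 0.329 to 0.611 with 1 library left out, and moved by less than its spread of 0.0913 otherwise. Over called genes, as first planned, it has a value only in settings with such genes. It was 0.571 with upper-quartile scaling, 0.514 with no filter, 0.518 with DESeq2, 0.512 with limma-voom, 0.551 with a replicate block, 0.663 with the immediate early covariate and 0.0315 to 0.682 with 1 of UNX/DOCA vehicle replicates 1 and 2 or UNX/DOCA ITF2357 replicates 1 and 2 left out.

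Of 24 lists called for UNX/DOCA vehicle against Sham vehicle, 0 stayed with an estimated correlation, 0 were called with fry and 7 kept their call and direction with replicates 3 and 4 left out, where 11 lists were called. For UNX/DOCA ITF2357 against UNX/DOCA vehicle, 19 became 0 with an estimated correlation, 3 with fry, 7 with replicates 3 and 4 left out (6 of them among the 19) and 10 to 26 with 1 library left out. For UNX/DOCA ITF2357 against Sham vehicle, 6 became 0 with an estimated correlation, 14 with no filter, 18 with the immediate early covariate and 6 to 10 with 1 library left out.

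With replicates 3 and 4 left out, medians against Sham vehicle reversed for complement (-0.10), class II (-0.0491), neutrophil (-1.36, called lower at a camera adjusted p of 0.0021, adjusted p = 0.785 with an estimated correlation) and chemokine genes (-0.26), and so did Fn1 (-0.0599) and Csf3r (-0.32). Under ITF2357 against UNX/DOCA vehicle, so did macrophage (0.10), protease (0.00865), neutrophil (0.23), class II (0.0814), other collagen (0.010), HDAC (0.00383) and HDAC inhibitor response genes (0.25), Fn1 (0.0535) and S100a8 (0.10). These 2 libraries have the highest neutrophil scores of the 12.

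Results near 0 changed sign without passing. For UNX/DOCA ITF2357 against UNX/DOCA vehicle the HDAC median was -0.10 to 0.0258 with 1 library left out, above 0 without UNX/DOCA vehicle replicates 2 and 3. The response list was -0.30 to 0.0601 with 1 library left out, above 0 without UNX/DOCA vehicle replicate 3 and UNX/DOCA ITF2357 replicate 3, and 0.00385 with the immediate early covariate. Nppb was -0.33 to 0.13 against Sham vehicle with 1 library left out, above 0 without UNX/DOCA vehicle replicate 2 and Sham vehicle replicate 3. For UNX/DOCA ITF2357 against Sham vehicle, Fn1 was 0.0287 with upper-quartile scaling, 0.00582 with library totals, 0.000614 with only the 2 groups compared, 0.22 with the immediate early covariate and -0.17 to 0.0859 with 1 library left out. Macrophage genes had a median of -0.23 with the clock covariate.

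No named gene that passed changed sign in any setting, which is likely for genes chosen by their call in the fit of all libraries. Of the 32 named genes called with ITF2357 against UNX/DOCA vehicle, 173 of 384 fits with 1 library left out kept the call and 211 lost it, and 258 of 379 fits with another setting kept it. Of the 10 named against Sham vehicle, 81 of 120 and 99 of 119 did. Totals of 23.4 to 34.9 M counts leave genes under about 1 CPM, such as Ccnb2 and Cd79b, with few reads per library, and their values are given with that limit.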

Other observations

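The clock covariate and immediate early covariate reported here were chosen after the data were seen. Libraries differed in the expression of clock genes. The first component of the clock list held 71.6% of its variance and was above 0 in 4 of 4 UNX/DOCA ITF2357 libraries (0.68 to 2.80), in 2 of 4 UNX/DOCA vehicle libraries and in 1 of 4 Sham vehicle libraries. As a covariate within groups it was associated with 6 genes, 1 of them outside the clock list it was built from, and the immediate early score with 63, 50 of them outside its list. The first principal component of all genes held 26.5% of the variance, and UNX/DOCA vehicle replicates 3 and 4 had the highest values on it (66.0 and 32.9).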
